A study of Triticum aestivum with 6 samples.

How the data were processed

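Roots of bread wheat (Triticum aestivum, wild type JW1) were profiled by RNA sequencing in 6 libraries, 3 from seedlings without nitrate (0N) and 3 from seedlings given nitrate (2N). Per the labels' protocols, seedlings germinated for 3 days, lost their endosperm by hand, grew for 3 days with 2 mM nitrate and for 2 days without nitrogen. They then stood for 3 hours in medium with 2 mM KCl (0N) or the potassium nitrate salt at 2 mM (2N; the labels spell it KNO). The added chloride thus differed between the groups together with nitrate, and effects of nitrate and of chloride cannot be told apart. Roots were extracted with TriZol, poly(A) RNA was enriched and random-primed, and circular single-stranded DNA libraries were sequenced, per the labels' protocols. No label states that the libraries keep the strand, so reads of overlapping genes on opposite strands cannot be told apart. The tissue label of every sample is root, while a cell line label reads leaf tissue. Replicates are numbered 1 to 3 in both groups, and no label says whether they are separate cultures or pools of plants, so p-values measure only the spread between samples.

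The authors' processing notes name HISAT and Bowtie2 without versions. The genome build, the annotation and the counting program are not given in the sources used here. The authors deposited estimated counts of reads per gene (expected counts) that are not normalized, and 45.1% of all values are not whole numbers (tolerance 1e-06). The authors also deposited TPM values scaled to the same total in each library, per the file headers and the column sums. The deposited table holds 83219 genes, each with the UniProt entry that diamond matched best. Gene names are these best matches and stand for similarity to a protein of wheat or another species, not for a curated wheat symbol. Of the descriptions, 240 were empty and 18725 uncharacterised. The reference table of 155467 wheat genes (assembly IWGSC CS RefSeq v2.1) matched 0 of the identifiers, so no coordinates are given and the chromosome is the code inside the identifier. 1480 genes carry the code for unplaced sequence.

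Expected counts were rounded to whole numbers. Genes were kept by filterByExpr of edgeR with the groups (minimum count 10, minimum total 15), which left 54313 of the 78172 genes with at least 1 count. Libraries were scaled by TMM and compared by edgeR's quasi-likelihood test with robust dispersion, 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05 on the adjusted p. Log2 fold changes are 2N against 0N. Their standard errors (SE) were back-calculated as the size of the log2 fold change divided by the square root of the test's F statistic. They are approximate and need not match the p-values, above all for genes near 0 counts in a group. CPM values use the TMM-scaled library sizes. A fold against a group at 0 counts was computed against a floor of 3 counts per library and is a lower bound. Floors cover counting error only. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and matplotlib 3.10.9.

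26 gene lists were fixed before the data were examined, as were the main test, the rule for named genes and the other settings to try. A gene belonged to a list when its description matched the list's search expression. Each list was tested as a set with limma's camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 26 lists, and beside it with an estimated correlation and with fry. Fry tests whether a list's genes move on balance in a single direction and does not compare them with other genes. Some expressions also matched unintended descriptions, so the lists were run again with those descriptions removed, a choice made after the descriptions were read and before any fit. Summed CPM values of a list were compared by a 2-sided exact permutation test, whose smallest possible p with 3 against 3 is 0.1.

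The rule named 3 kinds of gene. The first kind was the 8 largest rises and the 8 largest falls among genes past the threshold with a mean CPM of at least 5, groups that did not overlap and an informative description. The second was the 3 members with the smallest p past the threshold in each list, and the third the most abundant tested member of each of the marker lists. It gave 96 genes, of which 46 had counts that were not whole in all 6 libraries. A division of reads among similar genes can give such values, but their cause was not tested. In a hexaploid genome with homoeologous and tandem copies, the division between copies is uncertain.

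The fit was tested on simulated counts drawn from the real means and library sizes with 200 genes changed. The changed genes were picked only from those above a minimum mean count, so recovery among genes with the lowest counts was not measured. For 2N against 0N, with 54260 simulated genes tested, it recovered 32% of the genes changed 1.5-fold, 74% of those changed 2-fold, 98% at 4-fold and 100% at 8-fold, with 50 genes at each size and 0 wrong signs. 33 unchanged genes were also called, which was 17.8% of the calls. This is above the share of 0.05 that the threshold on the adjusted p is meant to allow. In this simulation the test thus called too many unchanged genes.

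Alternatives were RLE, upper-quartile and library-total scaling, DESeq2, limma-trend on log2 CPM and on the deposited TPM (log2 of the value plus 0.1), no filter and a stricter filter (CPM of at least 1 in at least 3 libraries), a replicate block, glmTreat against a fold of 1.5, and leaving out each library in turn. Membership by KEGG orthology and the enrichment of annotation terms were not run because the deposited table holds no such columns, and a comparison by the authors was not used here. After the fits had been seen, genes were also grouped into 825 families by the name of the best match (10 to 500 tested genes each) and tested by Fisher's exact test, 1-sided, for an excess of genes that rose or fell, adjusted over 1650 tests, with the 37529 tested genes that carry such a name as background. Homoeologues and tandem copies are not independent, which makes those p-values too small.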

Results

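The data are expected read counts per gene from 6 root libraries of bread wheat, 3 without nitrate (0N) and 3 after 3 hours with 2 mM nitrate (2N). The total count was 16208306 to 16426359 in the 0N libraries and 17234841 to 17645560 in the 2N libraries, with 69457 to 70776 genes detected in each. The 10 most abundant genes took 1.68% to 2.20% of a library. Spearman correlations of log2 CPM were 0.980 to 0.986 within groups and 0.951 to 0.960 between groups, and the first principal component, which separated the groups, held 59.4% of the variance. The comparison asks which transcripts of nitrogen-starved roots differ after a short nitrate supply, in a series that the labels place in work on nitrate and abscisic acid (ABA) in wheat roots.

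With nitrate, 25 of 31 genes of high-affinity nitrate uptake and 11 of 11 of nitrate and nitrite reduction rose, as did 10 of 34 of reductant supply and 14 of 60 of ammonium assimilation. As sets, only nitrate and nitrite reduction kept its call when the correlation between members was estimated. Early light-inducible protein, oxalate oxidase and cinnamoyl-CoA reductase transcripts stood among the largest falls. The summed level of the NRT2 and NAR2 genes was 260 ± 37.3 CPM in 0N and 5266 ± 1042 CPM in 2N (SD, n = 3), and that of nitrate and nitrite reductases was 267 CPM (SD 15, n = 3) and 3346 ± 138 CPM. Of 54313 tested genes, 4109 rose and 4306 fell by edgeR's quasi-likelihood test, together 15.5% of those tested. 1159 rose and 1721 fell with a log2 fold change of at least 1 in size. The groups did not overlap in 32.4% of all tested genes, against 10% by chance. In the changed genes, which were selected for a group difference in the same libraries, the share was 99.0%. Scaling by library totals in place of TMM gave 2920 rises and 6208 falls, and limma-trend on the deposited TPM gave 2465 rises and 5415 falls. Library totals moved the log2 fold change of the median gene by -0.10.

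**Figure D1:**
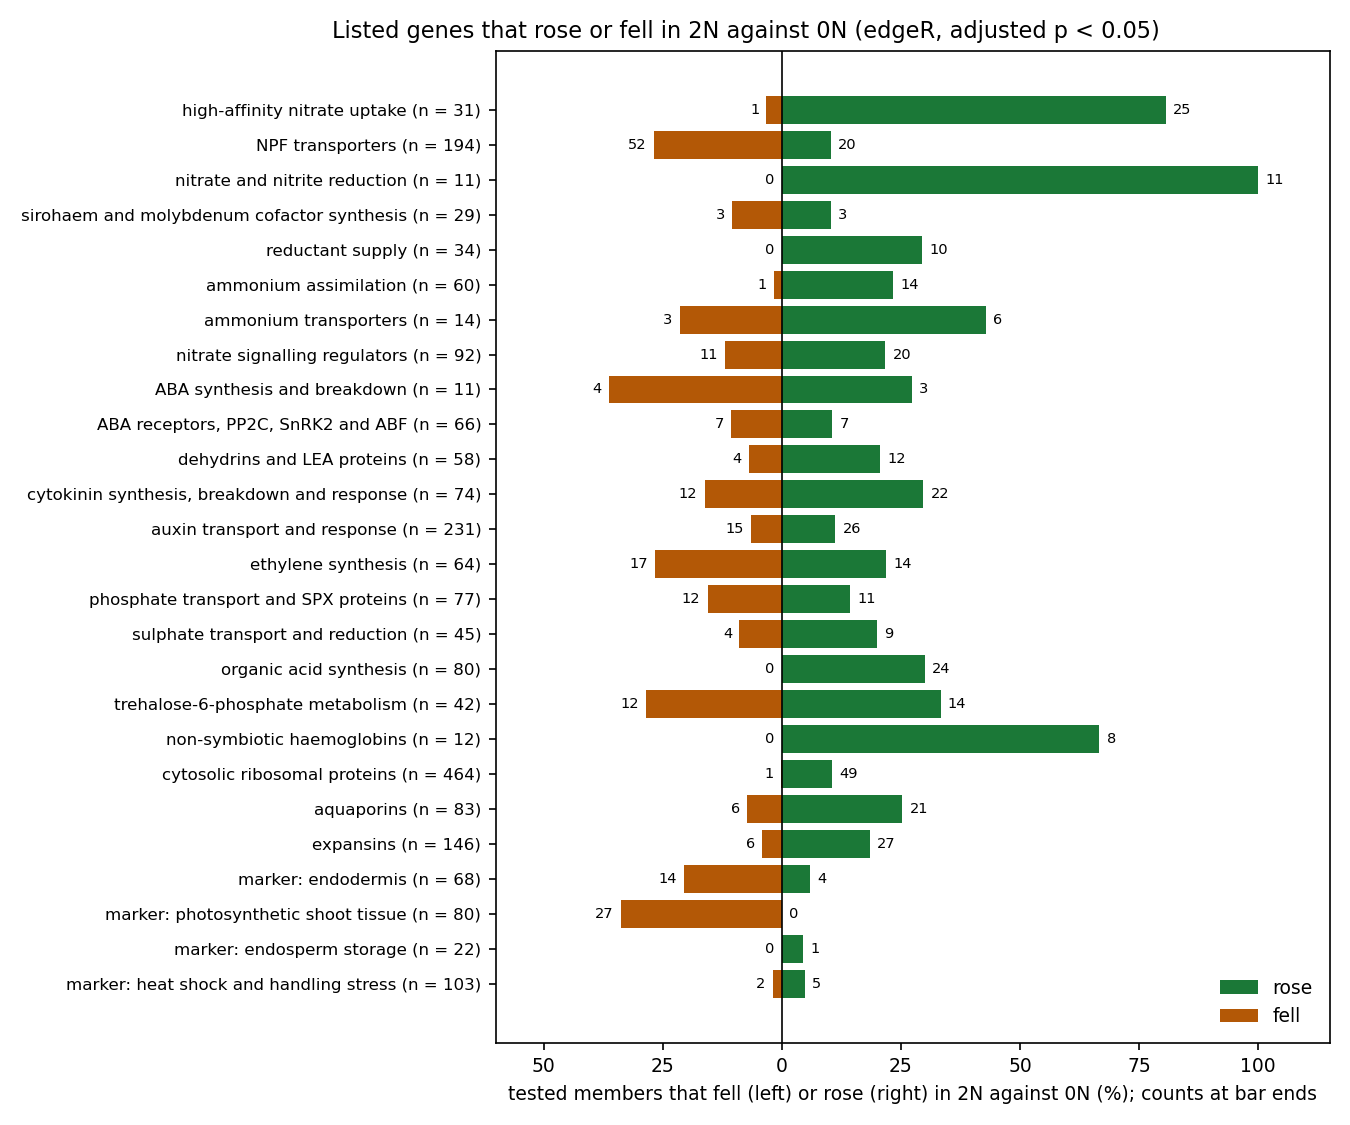
Share of the tested members of each of the 26 fixed gene lists that fell (left, orange) or rose (right, green) in 2N against 0N, in percent, with the number of genes at each bar end. All 11 nitrate and nitrite reductase genes and 25 of 31 NRT2 and NAR2 genes rose, while 27 of 80 photosynthetic marker genes fell.

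High-affinity nitrate uptake held the largest rises. NRT2 proteins carry nitrate into root cells at low external supply, and NAR2 proteins are the partners that they need. Of 31 tested genes, 25 rose and 1 fell (26 and 1 adjusted over the list alone), with a median log2 fold change of 6.52, or 6.44 with genes at 0 counts in 0N set to their bound. All 17 genes similar to NRT2.1, all 6 similar to NAR2.1 and both similar to NAR2.2 rose. The NRT2.1-like TraesCS6A02G031100 went from 1.06 ± 0.49 to 304 ± 77.6 CPM (log2 fold change 8.16 ± 0.33 SE, adjusted p = 5e-06), and TraesCS6B02G044000 from 0.914 ± 0.260 to 208 ± 50.8 CPM. All of the 8 largest rises that the rule named were NRT2.1-like genes on 6A, 6B and 6D. TraesCS6D02G035700 and TraesCS6B02G044200 had 0 counts in every 0N library. If counting error alone left them at 0, they were at least 392-fold and at least 382-fold higher in 2N. These bounds do not hold if reads were divided among similar genes. The adjusted p of these genes, 0.021 and 0.042, was 0.16 and 0.23 without 2N replicate 3. Without a filter it was 0.05 and 0.067, and neither gene passed. That of TraesCS6B02G044200 was 0.057 to 0.068 without a 0N library (ranges over the alternatives 1.4e-21 to 0.16 and 2.9e-20 to 0.23). The NAR2.1-like TraesCS6B02G238800 rose by 3.43 ± 0.14 (log2, SE; adjusted p = 1e-09). The gene that fell was 1 of the 3 similar to NRT2.3, with a log2 fold change of -1.01. The list was higher by camera (adjusted p = 1.8e-33), and its adjusted p was 0.198 with an estimated correlation.

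The NPF family carries nitrate, peptides and hormones. Of 194 tested members, 20 rose, 52 fell and 122 did not pass the threshold (20 rose and 58 fell adjusted over the list alone), with a median of -0.21 on the log2 scale. The summed level was 2617 ± 118 CPM in 0N and 2536 ± 102 CPM in 2N (exact permutation p = 0.5). Of the genes similar to NPF6.3, in Arabidopsis a transporter and sensor of nitrate, 6 of 9 rose and 1 fell, of those similar to NPF2.3 8 of 15 rose and 3 fell, and of those similar to NPF7.3 2 of 3 rose. The NPF6.3-like TraesCS1B02G225000 went from 22.9 ± 1.97 to 78.1 ± 9.73 CPM (log2 fold change 1.77 ± 0.11, adjusted p = 1e-07). 20 of the 58 tested genes whose best match was PTR2 fell, and the NPF5.2-like TraesCS1D02G147400 fell by 2.27 ± 0.17 on the log2 scale. The list was lower by camera (adjusted p = 3.9e-05), with an adjusted p of 0.369 under an estimated correlation. Among 14 ammonium transporters, 6 rose and 3 fell (7 and 3 adjusted over the list alone). The 3 genes similar to AMT1;1 all rose, such as TraesCS2A02G365000 by 0.93 ± 0.10, and all 3 similar to AMT3;2 fell, such as TraesCS5D02G519400 by 2.04 ± 0.17. As a set they did not pass camera (adjusted p = 0.084), with 0.0385 without 0N replicate 2, 0.0227 with library totals and a range of 0.0227 to 0.514 over the alternatives.

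The enzymes that turn nitrate into ammonium rose without exception. All 8 nitrate reductase genes and all 3 nitrite reductase genes tested rose (11 of 11 also adjusted over the list alone), with a median log2 fold change of 3.94. Nitrate reductase makes nitrite in the cytosol and nitrite reductase makes ammonium in the plastid. The NIA1-like TraesCS6A02G017500 went from 13.4 ± 2.21 to 206 ± 9.45 CPM (log2 fold change 3.94 ± 0.12, adjusted p = 3.5e-11), and TraesCS6A02G326200 from 8.25 ± 1.87 to 188 ± 15.3 CPM. The nitrite reductase genes together stood at 17.2 CPM in 0N and 1676 CPM in 2N. This was the only list past the threshold with an estimated correlation, and barely (adjusted p = 0.04998, and 1.8e-20 by camera with the preset correlation).

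Nitrite reductase needs sirohaem and electrons from ferredoxin. All 3 genes similar to the uroporphyrinogen-III methyltransferase that starts sirohaem synthesis rose, among them TraesCS3D02G225500, from 1.96 ± 0.41 to 90.2 ± 3.06 CPM (log2 fold change 5.52 ± 0.14, adjusted p = 8.7e-12). In their list of 29 genes for sirohaem and molybdenum cofactor, 3 rose and 3 fell (3 and 3 adjusted over the list alone), the 3 that fell being similar to molybdenum cofactor sulfurase. Without 0N replicate 2, 2N replicate 1 or 2N replicate 3 3 genes passed, all upward, and the list did not pass camera (adjusted p = 0.5; its median of -0.04 and the direction of the test differ in sign), though it passed upward by fry (adjusted p = 0.00586). In the reductant list, 10 of 34 genes rose and 0 fell (10 and 2 adjusted over the list alone). The plastidial pentose phosphate pathway feeds NADPH to ferredoxin, and all 3 tested copies rose of each of 6-phosphogluconate dehydrogenase 2, glucose-6-phosphate dehydrogenase 2 and the root form of ferredoxin-NADP reductase. TraesCS1A02G357200, similar to the first of these, went from 11.4 ± 0.19 to 354 ± 33.3 CPM (log2 fold change 4.95 ± 0.12, adjusted p = 8.7e-12). Summed over the list, the level was 1176 ± 28.5 CPM in 0N and 4247 ± 294 CPM in 2N, although the median member stood at 0.02 on the log2 scale, or -0.07 with library totals. Camera gave an adjusted p of 6.8e-05, and 0.236 with an estimated correlation.

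**Figure D2:**
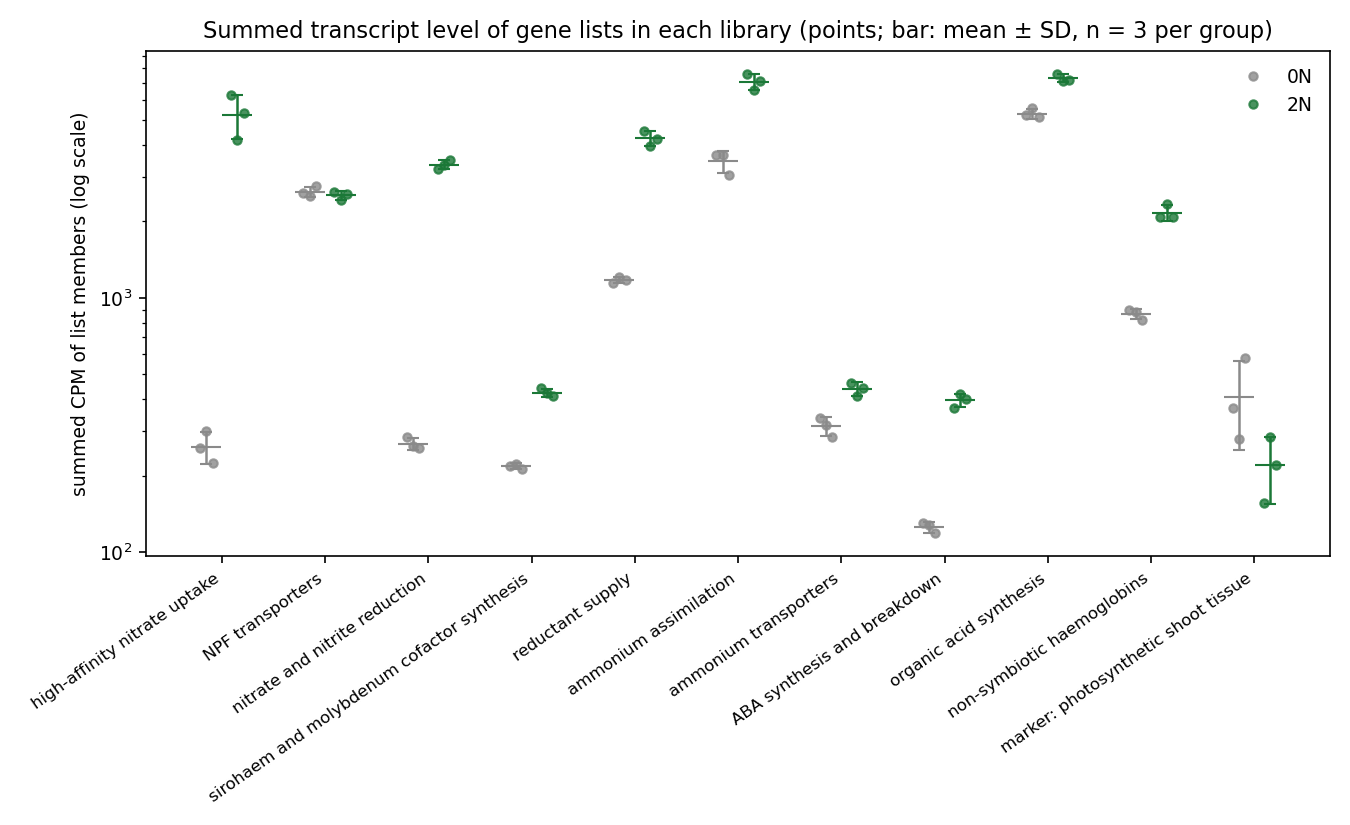
Summed CPM of the members of 11 lists in each library (points, log scale), with the mean and SD of 3 libraries per group (bars), for 0N (grey) and 2N (green). The nitrate and nitrite reduction sums lie near 267 CPM in 0N and 3346 CPM in 2N, while the photosynthetic marker sums of the groups overlap.

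Ammonium assimilation, which builds glutamine and glutamate, had 14 rises and 1 fall among 60 tested genes (14 and 1 adjusted over the list alone). With mismatched descriptions removed, 14 of 43 tested genes rose and 1 fell. Rises covered all 3 genes similar to NADH-dependent glutamate synthase, all 3 similar to ferredoxin-dependent glutamate synthase and 4 of 6 similar to plastidial glutamine synthetase. TraesCS2D02G500600, similar to the plastidial glutamine synthetase, went from 30.3 ± 3.80 to 351 ± 5.87 CPM (log2 fold change 3.54 ± 0.11, adjusted p = 3.5e-11), and the NADH-type synthase gene TraesCS3B02G299800 rose by 3.35 ± 0.11. The gene that fell was 1 of 12 similar to asparagine synthetases. The list was higher (camera adjusted p = 3.9e-05), with an adjusted p of 0.369 under an estimated correlation. Organic acid synthesis, which supplies carbon skeletons, had 24 rises and 0 falls among 80 genes (25 and 1 adjusted over the list alone). The plastidial malate dehydrogenase gene TraesCS1D02G351500 rose by 2.42 ± 0.10 and the phosphoenolpyruvate carboxylase gene TraesCS7B02G237900 by 2.20 ± 0.11 (adjusted p = 6.6e-10 and 3.8e-09). Camera gave 2.2e-06, and an adjusted p of 0.449 with an estimated correlation.

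Non-symbiotic haemoglobins, which bind and turn over nitric oxide, had 8 rises and 0 falls among 12 genes (9 and 0 adjusted over the list alone). 2 of the 8 were similar to a leghaemoglobin reductase, which is not a haemoglobin. TraesCS4B02G237300 went from 101 ± 8.13 to 653 ± 45.4 CPM (log2 fold change 2.70 ± 0.11, adjusted p = 3.9e-10), and TraesCS1D02G340600 rose by 5.25 ± 0.23. Camera gave 3e-07, and an adjusted p of 0.198 with an estimated correlation. In sulphate transport and reduction, 9 of 45 genes rose and 4 fell (11 and 4 adjusted over the list alone). The rises held all 3 genes similar to sulphite reductase, which also needs sirohaem, and all 3 similar to adenylylsulphate reductase, the sulphite reductase gene TraesCS1D02G324200 by 1.10 ± 0.09. 3 of 6 genes similar to the sulphate importer SULTR1;2 fell, among them TraesCS5B02G228500 by 2.02 ± 0.20. The list's camera p was 0.024 after adjustment, with an adjusted p of 0.357 under an estimated correlation and 0.0751 under the stricter filter.

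Among regulators of the nitrate response, 20 of 92 genes rose and 11 fell (22 and 17 adjusted over the list alone). All 3 genes similar to LBD39, in Arabidopsis a repressor of nitrogen-responsive genes, rose, TraesCS4A02G236200 among them from 0.796 ± 0.360 to 34.0 ± 5.51 CPM (log2 fold change 5.41 ± 0.22, adjusted p = 1.3e-08). Both genes similar to HHO5, of the family of nitrate-inducible GARP repressors, rose, TraesCS5D02G411800 by 2.40 ± 0.13. 6 of 8 genes similar to NLP1, of the family whose member NLP7 senses nitrate in Arabidopsis, fell, while the tested gene similar to NLP7 itself rose by 1.64 (log2) and 2 of 5 similar to NLP3 rose. The list did not pass camera (adjusted p = 0.15), and its median of 0.03 became -0.06 with library totals. Its expression also matched xylan glucuronosyltransferases and chaperonin-like proteins, of which 2 rose and 2 fell. With such descriptions removed, 18 of 58 genes rose and 9 fell, and the adjusted p was 0.00981 with the preset correlation but 0.255 with an estimated one. Over the alternatives, the adjusted p of the full list ran from 0.00745 by fry to 0.449 with an estimated correlation.

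ABA genes moved in both directions. All 3 genes similar to ABA 8'-hydroxylase, the main enzyme of ABA breakdown, rose, from a summed 90.7 CPM in 0N to 372 CPM in 2N. TraesCS6B02G298500 among them rose by 2.67 ± 0.15 and TraesCS6A02G271300 by 2.03 ± 0.10 (adjusted p = 1.9e-07 and 4.7e-09). Of the genes of ABA synthesis, all 3 similar to zeaxanthin epoxidase and the tested gene similar to NCED3, the rate-limiting dioxygenase, fell, the last from 0.892 to 0.320 CPM with a log2 fold change of -1.47. Of 4 genes similar to NCED1, of the same enzyme family, 0 passed the threshold, and their sum was 5.19 CPM in 0N and 4.64 CPM in 2N. In all, 3 of 11 genes of synthesis and breakdown rose and 4 fell (3 and 5 adjusted over the list alone), and 4 in all passed without 2N replicate 3 or with DESeq2. The list did not pass camera (adjusted p = 0.68) but passed upward by fry (adjusted p = 0.00217), and its median of -0.30 had the opposite sign to both tests. Among 66 genes of ABA perception and signalling, 7 rose and 7 fell (8 and 12 adjusted over the list alone). The 7 that rose were all similar to the ABA receptor PYL4, such as TraesCS1D02G293600, from 16.1 ± 2.41 to 45.1 ± 2.76 CPM (log2 fold change 1.48 ± 0.11). The 7 that fell were similar to SnRK2 protein kinases and bZIP factors of the ABA response. Camera gave an adjusted p of 0.62. Among dehydrins and late embryogenesis abundant proteins, which accumulate under water deficit, 12 of 58 rose and 4 fell (13 and 4 adjusted over the list alone). All 6 genes similar to LEA6 rose, TraesCS7D02G059600 from 70.8 ± 14.6 to 151 ± 11.5 CPM. 2 of the 12 were protein kinases named for a cold response, and the list did not pass camera (adjusted p = 0.12), its median of 0.01 becoming -0.08 with library totals. With mismatched descriptions removed, 10 of 36 genes rose and 4 fell. The median was then 0.18, and the list still did not pass camera (adjusted p = 0.062).

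Cytokinin genes of activation and of breakdown moved in both directions. All 6 genes similar to LOGL5, an enzyme that activates cytokinins, fell, TraesCS5B02G561300 from 23.9 ± 3.59 to 3.04 ± 0.52 CPM (log2 fold change -2.97 ± 0.15, adjusted p = 1.1e-08). Of the same enzyme family, 1 of 3 similar to LOGL1 and 1 of 2 similar to LOGL6 rose, and 1 of 2 similar to LOGL7 fell. All 3 genes similar to the cytokinin dehydrogenase CKX3 rose, TraesCS1D02G157000 by 2.41 ± 0.20, as did 2 of 3 similar to CKX5, while 1 of 2 similar to CKX4 fell. All 5 tested genes similar to the isopentenyltransferases IPT1 and IPT5, which start cytokinin synthesis, rose. Over the list, 22 of 74 rose and 12 fell (24 and 17 adjusted over the list alone), without passing camera (adjusted p = 0.23), and the median of 0.02 became -0.07 with library totals. In the auxin list, 26 of 231 genes rose and 15 fell (26 and 15 adjusted over the list alone). TraesCS1A02G425100, similar to GH3.5, which in rice links jasmonate and not auxin to amino acids, rose by 0.98 ± 0.11, and the auxin response factor 19 gene TraesCS7D02G409700 by 0.65 ± 0.09. 5 of 6 genes similar to the factor listed as ARFD fell. Camera gave 0.12, with 0.0343 without 2N replicate 2 and a range of 0.0343 to 0.514 over the alternatives, and the median of 0.05 became -0.04 with library totals. In ethylene synthesis, 14 of 64 genes rose and 17 fell (15 and 23 adjusted over the list alone), 20 in all without 2N replicate 3. The aminocyclopropane carboxylate (ACC) oxidase gene TraesCS4A02G221300 rose by 1.91 ± 0.15, as did all 3 genes similar to the ACC synthase 1A17. 10 of the 17 that fell and 1 of the 14 that rose were matched only to ACC oxidase homologs, 9 of the falls to homolog 1, and without these matches 13 of 31 rose and 7 fell. The full list did not pass camera (adjusted p = 0.055), which moved between 0.0106 without 2N replicate 3 and 0.525 over the alternatives, with 0.0388 without 0N replicate 2, 0.0366 without 2N replicate 1 and 0.0284 without a filter.

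Among phosphate transporters and SPX proteins, 11 of 77 rose and 12 fell (13 and 14 adjusted over the list alone). Without glycerol phosphate and mitochondrial carriers, which the list also matched, 7 of 55 rose and 8 fell. 4 of 7 genes similar to the phosphate transporter PHT1;8 fell, TraesCS5D02G472000 by 1.32 ± 0.13, and TraesCS5D02G243700, similar to a mitochondrial phosphate carrier, fell by 2.07 ± 0.22. Camera gave 0.88, and the median of 0.02 differed in sign from the test and became -0.07 with library totals. In trehalose 6-phosphate metabolism, which tracks sucrose supply, 14 of 42 rose and 12 fell (14 and 13 adjusted over the list alone). All 8 genes similar to the phosphatase RA3 fell, from a summed 206 CPM to 79.8 CPM, while all 3 similar to the phosphatase TPP1 rose, TraesCS6B02G276300 by 2.07 ± 0.13 (adjusted p = 7.2e-08). Camera gave 0.5 for the list, and its median of -0.04 differed in sign from the test.

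A minority of the genes of protein synthesis, water transport and wall loosening rose. 49 of 464 cytosolic ribosomal protein genes rose and 1 fell (17 and 0 adjusted over the list alone), with a median of 0.21, and the gene with the smallest p, TraesCS5A02G032000 (S20), rose by 0.43 ± 0.09. The number changed, 50, was 9 without 0N replicate 1, 24 without 0N replicate 3, 12 without 2N replicate 1, 9 without 2N replicate 3 and 128 without 0N replicate 2, 16 with library totals and 22 with the replicate number as a block. The camera p of 3e-12 became an adjusted p of 0.514 with an estimated correlation and 0.0974 by fry. Of 83 aquaporins, 21 rose and 6 fell (32 and 9 adjusted over the list alone), among them the PIP2-6-like TraesCS5A02G100000, from 35.5 ± 0.28 to 70.0 ± 2.94 CPM (log2 fold change 0.98 ± 0.09). The number changed, 27, was 15 without 0N replicate 1 and 16 without 0N replicate 3, 2N replicate 1 or 2N replicate 3, and the camera p of 0.001 became an adjusted p of 0.506 with an estimated correlation and 0.0575 by fry. Of 146 expansins, which loosen cell walls, 27 rose and 6 fell (28 and 8 adjusted over the list alone), the EXPA1-like TraesCS2B02G078800 by 1.97 ± 0.17. The number changed, 33, was 18 without 0N replicate 1 and 19 without 2N replicate 1. The camera p of 0.0027 was 0.112 without 2N replicate 3, and the adjusted p was 0.515 with an estimated correlation and 0.187 by fry.

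Markers of other tissues and of handling were measured in the same way. Of 80 photosynthetic marker genes, 0 rose and 27 fell (0 and 40 adjusted over the list alone), with a median of -0.93. The chlorophyll a-b binding protein gene TraesCS2A02G204800 went from 4.84 ± 0.40 to 1.86 ± 0.36 CPM (log2 fold change -1.37 ± 0.19, adjusted p = 0.00019). The most abundant, TraesCS2D02G248400 (oxygen-evolving enhancer protein 1), fell by 0.84 ± 0.22 (adjusted p = 0.04). Its adjusted p was 0.13 without 0N replicate 1, 0.073 without 0N replicate 3, 0.14 without 2N replicate 3 and 0.1 without a filter (range over the alternatives 5e-04 to 0.14). The summed level was 409 ± 156 CPM in 0N and 219 ± 64.4 CPM in 2N and overlapped between groups (exact permutation p = 0.2). The number that fell, 27, was 15 without 0N replicate 1, 46 without 0N replicate 2, 15 without 0N replicate 3, 11 without 2N replicate 1 and 8 without 2N replicate 3. Camera gave 1.1e-13, and the adjusted p was 0.449 with an estimated correlation and 0.0974 by fry. Of 68 genes in the endodermis list, 4 rose and 14 fell (6 and 14 adjusted over the list alone), with a camera p of 0.038 and a call that was lost in 5 of 14 alternatives and turned upward in 1. Its adjusted p was 0.449 with an estimated correlation, 0.102 without a filter, 0.0762 without 2N replicate 2, 0.0575 by fry and 0.0568 with library totals. The 14 were CASP-like proteins, which are not specific to the endodermis, such as TraesCS1D02G248200, which fell by 1.22 ± 0.15. Of the 6 Casparian strip proteins proper, 4 rose and 0 fell, TraesCS7D02G324700 by 0.74 ± 0.11, and taken alone they were higher by camera with the preset correlation (adjusted p = 0.000592), a call that was lost with an estimated correlation (adjusted p = 0.403). Of 22 endosperm storage genes, 1 rose, a serpin (TraesCS4D02G308100, log2 fold change 1.68 ± 0.24), and 0 fell (1 and 0 adjusted over the list alone), and 2 passed under 5 of the alternatives. Serpins are also made in vegetative tissue, and without them 5 genes were left, of which 0 passed, with a median of -0.16. The most abundant of the 22, the serpin TraesCS4B02G079200, stood at 19.5 ± 0.93 and 20.9 ± 0.40 CPM, and camera gave 0.23 with a median of 0.07 that became -0.03 with library totals. Of 103 heat shock genes, 5 rose and 2 fell (4 and 0 adjusted over the list alone), 4 in all without 0N replicate 1 or 2N replicate 3 and 12 without 2N replicate 2 or without a filter. A small heat shock protein gene, TraesCS1D02G319400, rose by 1.39 ± 0.17, while the most abundant, the HSP70 gene TraesCS5B02G492500, stood at 1434 ± 126 and 1470 ± 34.5 CPM. The camera p of 0.0094 was 0.131 without a filter and 0.0545 without 0N replicate 2, and the adjusted p was 0.064 by fry and 0.449 with an estimated correlation.

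**Figure D3:**
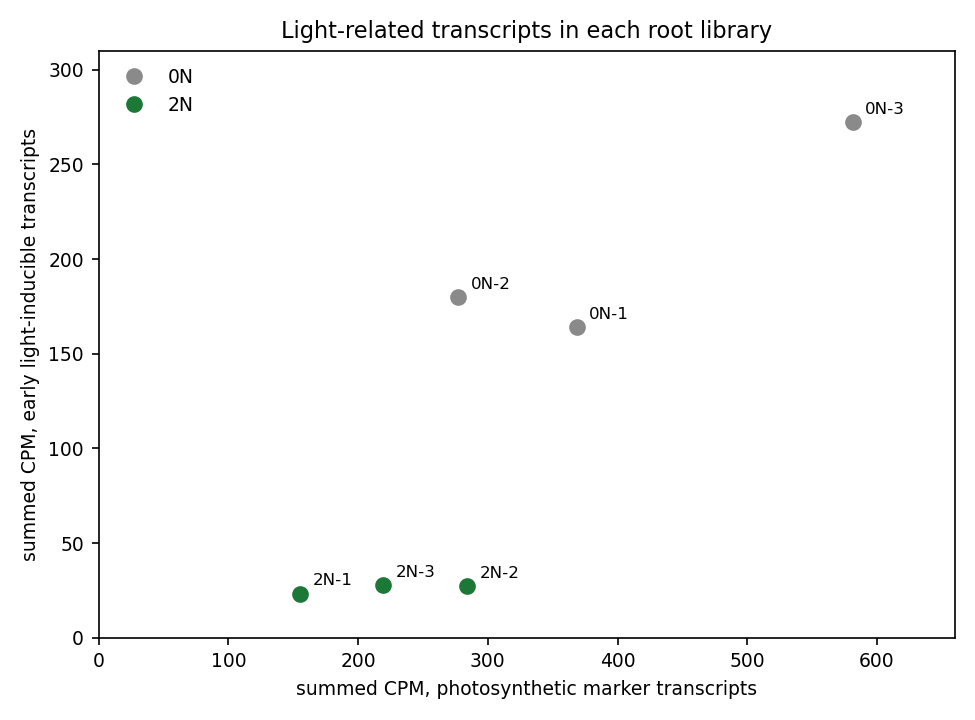
Summed CPM of the early light-inducible transcripts (vertical axis) against summed CPM of the photosynthetic marker transcripts (horizontal axis) in each of the 6 root libraries, 0N in grey and 2N in green. The early light-inducible sums lie at 164 to 272 CPM in 0N and 23.4 to 27.8 CPM in 2N, while the marker sums of the groups overlap.

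The largest falls that the rule named were in early light-inducible proteins and in genes of phenylpropanoid and oxalate metabolism. TraesCS5B02G218600, similar to a low molecular mass early light-inducible protein of barley, went from 16.2 ± 6.56 to 0.395 ± 0.243 CPM (log2 fold change -5.32 ± 0.52, adjusted p = 0.0013). Its neighbours by identifier TraesCS5B02G218500 and TraesCS5B02G218200 also fell, with log2 fold changes of -3.42 ± 0.18 and -3.34 ± 0.19. The photosynthetic marker sum, 409 ± 156 CPM in 0N and 219 ± 64.4 CPM in 2N, was also lower in 2N on average. The cinnamoyl-CoA reductase genes TraesCS6A02G381400 and TraesCS6B02G420300, of monolignol synthesis, had log2 fold changes of -3.76 ± 0.26 and -3.47 ± 0.47. The oxalate oxidase genes TraesCS4B02G033100 and TraesCS4A02G279100, whose product releases hydrogen peroxide, had log2 fold changes of -3.58 ± 0.50 and -3.32 ± 0.36, and the methyltransferase gene TraesCS2D02G047500 fell by 3.35 ± 0.17.

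**Figure D4:**
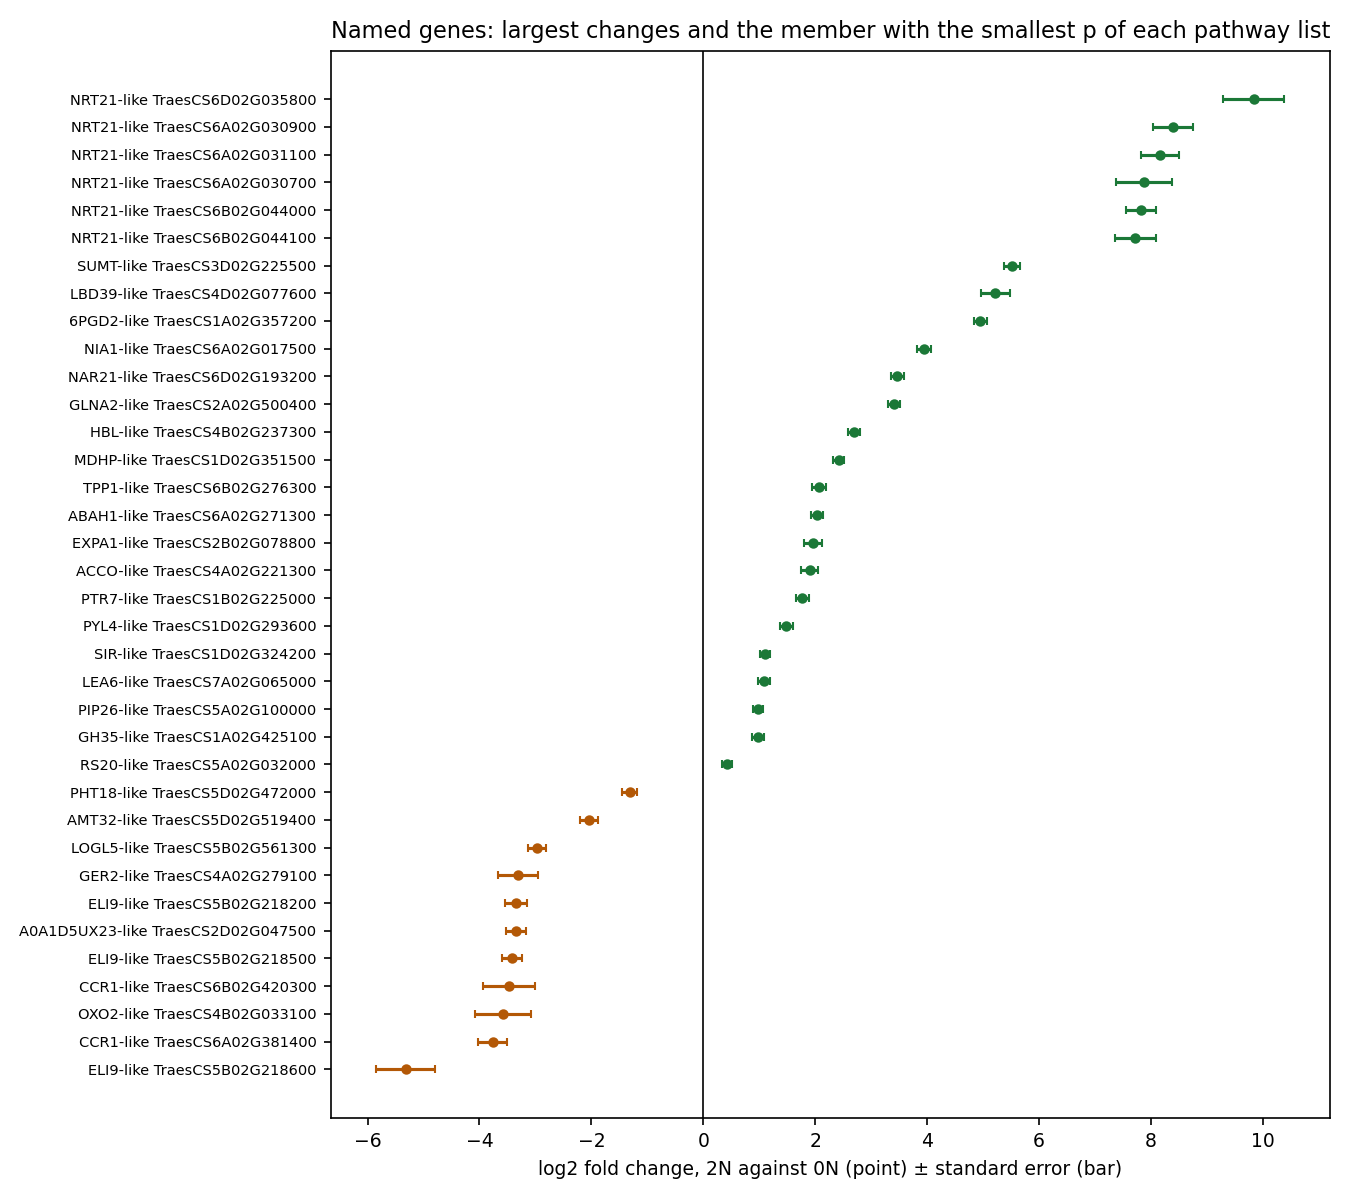
Log2 fold change of 2N against 0N (points) with its standard error (bars) for 36 named genes, labelled by best match and identifier, with rises in green and falls in orange. They run from -5.32 for an early light-inducible protein gene to 9.84 for an NRT2.1-like gene, and the genes at 0 counts in 0N are left out.

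The response was spread over the A, B and D subgenomes, as the identifiers give them. The genes that rose were 7.78% of 17688 tested A genes, 7.10% of 17866 B genes and 7.92% of 18126 D genes, and those that fell were 7.77%, 7.71% and 8.25%. The share of all counts on each subgenome was 32.7%, 32.2% and 34.2% in 0N and 32.6%, 32.2% and 34.3% in 2N. These shares were not tested, since genes are not replicates.

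By camera with the preset correlation, 14 of 26 lists passed the threshold, 11 higher and 3 lower in 2N, and 580 of the 2191 list members changed, 63.1% of them upward. Of all changed genes, 48.8% rose. With library totals the upward shares were 51.4% of the changed members and 32.0% of all changed genes. For each of the 13 lists that lost their call with an estimated correlation, that p was the highest of its 14 alternatives. In those 13 the lowest p over the alternatives ran from 3.61e-41 for high-affinity nitrate uptake to 0.0122 for sulphate transport and reduction.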

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

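The repeat without mismatched descriptions and the repeats for name families, early light-inducible genes and NRT2.1 copies were chosen after seeing the data, and the others before. The number of genes changed stayed within 1.5 times the reported 8415 under every alternative but glmTreat against a fold of 1.5, which tests a stricter hypothesis and gave 1954, and was 5704 to 8152 with a library left out. Library totals gave 32.0% rises among the changed genes, against 48.8% as reported, because they moved the log2 fold change of the median gene by -0.10 and the list medians by about as much. The deposited TPM, also scaled to the same total in each library and used without TMM, gave 31.3% rises with a median gene at -0.10. Whether anything beyond this scaling contributed was not tested. The list members changed, 580 as reported, were 407 to 673 with a library left out and 507 to 638 under the other alternatives. The lists past the threshold, 14 as reported, were 14 or 15 with a library left out, 11 by fry, which lost 6 of the 14 and gained 3 others, and 1 with an estimated correlation, which counts the correlation between members as a reason for wider errors. With mismatched descriptions removed, 15 lists passed, and the endodermis list turned from lower to higher (adjusted p = 0.000592, and 0.403 with an estimated correlation) because the CASP-like proteins that fell were no longer in it.

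Of 1440 values of named genes under the alternatives, 1424 kept their direction and their side of the threshold, and 91 of 96 genes did so throughout. 11 values lost the call, all of the genes TraesCS6D02G035700, TraesCS6B02G044200 and TraesCS2D02G248400. 5 values changed sign, in genes that were not past the threshold: TraesCS4B02G079200 on the deposited TPM (-0.0077), and TraesCS5B02G492500 with library totals (-0.0598), on the deposited TPM (-0.0672), without 0N replicate 1 (-0.0077) and without 0N replicate 2 (-0.0196), its values with a library left out running up to 0.0955, and the cause was not tested. The subgenome medians, near 0 as reported, were -0.09 each with library totals.

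With the replicate number as a block, 7299 genes, 507 members and 14 lists passed. No pairing by number was seen. Same-numbered libraries had correlations of -0.0052, -0.11 and 0.026 between their deviations from the group means, and those of different number -0.10 to 0.11. Of 6 samples, 1 correlated best with its own number. With 3 libraries per group a weak shared effect could be missed, so pairing is not excluded. In simulated data with 200 genes changed, 32% of changes of 1.5-fold and 74% of changes of 2-fold were recovered at this depth and number of libraries. Genes with the lowest counts were not among those changed. The real data had 8415 genes called, which makes the threshold on the unadjusted p less strict, so these shares do not carry over directly. Changes under 2-fold can still lie among the genes not called. Unchanged genes made up 17.8% of the simulated calls, above the share of 0.05 that the threshold on the adjusted p is meant to allow. Their share among the 8415 real calls was not measured and may also be above it.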

Other observations

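The name families, the tests on early light-inducible transcripts and on NRT2.1 copies, and the scaling tests were chosen only after the results had been seen. Grouped by best match, 55 of 825 families held an excess of genes that rose and 68 an excess that fell. Peroxidases, which build and loosen walls with hydrogen peroxide, had 153 rises and 39 falls among 430 genes (Fisher's exact test, adjusted p = 1.3e-56 for the rises), and 101 rises without 0N replicate 1. The peroxidase gene TraesCS2B02G125700 rose by 2.50 ± 0.17 on the log2 scale. 8 of 10 S-type anion channel genes, of the family that releases chloride and nitrate from cells, rose (adjusted p = 5.6e-06), or 5 with limma-trend on the deposited TPM, as did 9 of 14 arabinogalactan protein genes (adjusted p = 1.2e-05). Glutathione transferases, which conjugate and detoxify reactive compounds, had 94 falls and 9 rises among 186 genes (adjusted p = 2.4e-47), with the gene TraesCS7D02G044500 falling by 2.47 ± 0.11.

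30 of 45 genes of phenylalanine ammonia-lyase, the entry to phenylpropanoids, fell and 0 rose (adjusted p = 3.4e-19), although their summed level was 8016 ± 663 CPM in 0N and 7499 ± 112 CPM in 2N (SD, n = 3). There were falls in 17 of 21 oxalate oxidase genes (adjusted p = 8.1e-13), whose summed level was 273 ± 85.8 CPM in 0N and 68.6 ± 10.2 CPM in 2N (SD, n = 3). Falls were also in excess among L-type lectin receptor kinases (36 of 81), UDP-glycosyltransferases (45 of 151), amino-acid permeases (10 of 16) and chitinases (15 of 28, and 9 without 2N replicate 2). Each of the excesses named here stayed past the threshold under every alternative run for it, which left out glmTreat, with adjusted p of at most 0.0063.

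The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. Only 1 of them, the real split, gave as many as 8415 changed genes and 14 lists past camera, and the highest of the others gave 0 and 11. With 0 genes called, the other splits could give 0 changed list members and 0 name families and nothing else, so they add nothing on the 580 members and the 123 families of the real split. A split that mixes the groups can pass 11 lists by camera with the preset correlation while calling 0 genes by edgeR.

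Photosynthetic marker transcripts were lower in 2N by a median of 0.93 on the log2 scale, with sums per library from 277 to 581 CPM in 0N and from 155 CPM upward in 2N, where 2N-2 lay above 0N-2. Library totals in place of TMM shifted this median by only -0.10, to -1.03, so the choice between them was too small to make the difference. The median of all tested genes shifted by as much, so this repeat could not have come out otherwise. A candidate source is shoot tissue carried into the root samples in differing amounts, which would bring other abundant shoot transcripts with it. A test fixed before its result was seen used 38 genes outside the list, of the Calvin cycle, the light reactions and chlorophyll synthesis (magnesium chelatase). They had a median of -0.83 (95% interval -1.02 to -0.61 from resampling the genes), below -0.47, the bound set for that source. Only 4 of them fell past the threshold. The interval treats the genes as independent and leaves out the spread between libraries. Their sums were 199 ± 42.1 CPM in 0N and 156 ± 17.4 CPM in 2N, with 2N-2 at 173 CPM above 0N-2 at 165 CPM, and their most abundant members, similar to a photosynthetic NDH subunit, had log2 fold changes of 0.07 to 0.18, which a small share of shoot cells may not move. Lower expression of these genes within the roots under nitrate, the difference that the design names, predicts the same and stays open.

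Early light-inducible transcripts, which plants make under strong light and during greening, fell in 17 of 18 tested genes, and the log2 fold changes of the 18 ran from -5.32 to -1.89. Their summed level was 205 ± 58.3 CPM in 0N and 26.2 ± 2.43 CPM in 2N (SD, n = 3). The log2 ratio of the sums was -3.07 with library totals, which moved the median gene by only -0.10. The choice between TMM and library totals was thus too small to make this difference. Shoot tissue as the whole cause is argued against, within limits. Beside a straight line on the photosynthetic marker sum over the 6 libraries, 68.8% ± 15.9 (SE) of the difference between the groups was left. A single unchanged source would leave none only if the marker sum measured it without error, and the fit rests on 6 libraries. The ratio of the early light-inducible sum to the marker sum was 0.521 ± 0.111 in 0N and 0.125 ± 0.027 in 2N (SD, n = 3). A response of the roots to nitrate, the difference that the design names, and shoot cells whose own transcripts differ between the groups stay open and may act together.

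The NRT2.1-like genes share a best match, and the counting may have had to divide reads among them. How alike their sequences are was not measured, and the 8 named ones had counts that were not whole in 3 or 4 of the 6 libraries. A division among them may move counts from gene to gene but cannot raise their sum. The sum over the 31 such genes in the table was 10.3 ± 3.71 CPM in 0N and 1947 ± 516 CPM in 2N (SD, n = 3), a log2 ratio of 7.56. The rise of this sum, which includes the genes that were not tested, argues against division among these genes alone as the cause. The rise of all 17 tested ones is no separate test, since the sum had to rise with them. A gene near 0 in 0N could also pass the filter only through its 2N counts. Reads shared with genes outside this group were not examined. For the genes at 0 counts in all 0N libraries the question cannot be settled. TraesCS6D02G035700 and TraesCS6B02G044200 took 7.40% of these genes' counts in 2N, a share that would give 38.4 counts over the 3 libraries of 0N, so either the division of reads or a different use of the genes may have left them at 0.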
